A study of Mus musculus with 9 samples.

How the data were processed

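RNA was measured in hippocampal tissue of C57BL/6J mice, in 9 libraries that the labels divide into 3 groups of 3. Sham mice had a spinal nerve exposed but not tied and were given solvent. SNL mice had spinal nerve ligation, a surgical model of neuropathic pain, and solvent. CBD mice had the ligation and then intraperitoneal cannabidiol, a non-intoxicating cannabinoid, at 5 mg/kg for 15 days. Per the labels' protocols, total RNA was taken with TRIzol and libraries were made from 1.3 ug with a SMARTER mRNA-seq kit. The labels do not say whether the libraries of a group came from separate animals, so the p-values below measure only the spread between these samples, which may be technical.

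The deposited table holds expected counts per gene for each library, the estimated counts that RSEM gives when it shares reads among the transcripts they fit, and RSEM and the mouse build GRCm39 are named in the submitters' processing notes. The version of RSEM, the aligner, the gene annotation and any read filter are not given in the sources used here. Among genes with a total above 0, between 18.3% and 24.8% of the values of a library were not whole numbers. All values were rounded to whole numbers before any test. The table pairs gene identifiers with symbols, 1606 of its 57010 genes had no symbol, and 24417 genes had a total of 0. Symbols and identifiers are those of the table. Nnt has 2 entries in it whose shares differ between libraries, from 1.17 to 19.4 CPM for the first, while their sum ran from 17.2 to 20.8 CPM, so reads of genes with copies may be shared unevenly. The annotation at hand was of an older build, so no coordinates are given. It served only for transcript GC content and length, which 98.2% of the tested genes had.

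Genes were kept by edgeR's filterByExpr, which left 17967, and libraries were scaled by trimmed mean of M-values (TMM). The main test was edgeR's quasi-likelihood F test (version 4.0.16, R 4.3.3) with 1 factor for the 3 groups over all 9 libraries and 6 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the 17967 genes, and the threshold was an adjusted p under 0.05. Fold changes are on the log2 scale with their standard errors (SE), where the SE is the fold change divided by the square root of the F statistic. CPM values are the rounded counts of a gene scaled by the TMM-adjusted library size as edgeR's cpm function does, and are given as mean ± SD. The common biological coefficient of variation was 0.192.

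Before the data were examined, 44 gene lists were fixed, 16 for cell types and tissues the dissection could hold and 28 for pathways. Each was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset correlation between genes of 0.01 and adjustment over the 44 lists. Camera asks whether a list moved against all other genes. The same test with a correlation estimated from the residuals, and fry, which asks whether the genes of a list move one way on balance, were run as alternatives. For each list the number of members with an adjusted p under 0.05 was also counted with the p-values adjusted over the list alone.

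The genes named were chosen by a rule written before the data were examined. For each comparison it took up to 8 genes in each direction past the threshold. With fewer than 3 passing, it took instead the 5 smallest p-values in each direction among genes with a mean of at least 1 CPM and a gene symbol that is not a clone or pseudogene name. This applied to all 3 comparisons, and these genes missed the threshold. It added up to 4 members with the smallest p from each list described and 14 anchors: Bdnf, Cnr1, Faah, Trpv1, Htr1a, Gfap, Aif1, Fos, Arc, Fkbp5, Il1b, Tnf, Ttr and Drd2.

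The main test was tried on simulated data with 200 genes changed among the 17967. For SNL against sham it recovered 14.9% of genes changed 1.5-fold, 73.1% of those changed 2-fold and 89.4% of those changed 4-fold. The shares were 13.4%, 56.7% and 95.5% for CBD against SNL and 17.9%, 52.2% and 92.4% for CBD against sham. Genes simulated as unchanged made up 4.8%, 6.7% and 8.3% of the edgeR calls in the 3 comparisons in that order, and 20.3%, 20.5% and 23.4% of the DESeq2 calls. Camera found both of 2 shifted lists in each comparison and called 0 others. The simulation drew each gene on its own and leaves out the correlation between genes of a list. It therefore cannot show how often camera calls unshifted lists in these libraries.

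Alternatives chosen before the data were examined were DESeq2 size factors in the same edgeR fit, no filter on low counts, a filter of 1 CPM in 3 libraries, the DESeq2 Wald test (1.42.0), limma voom with sample weights, fits on only the 6 libraries compared, the replicate number as a block, 1 surrogate variable from sva (3.50.0), a fold threshold of 1.5, an adjusted p under 0.1, both other list tests, and each library left out in turn. Chosen after seeing the data were offsets for GC content and length, a covariate made from 23 hypothalamic marker genes, and a fit without the 3 libraries with hypothalamic transcripts. That fit leaves SNL 3 as the only SNL library, so it cannot test comparisons with SNL, and only its effect sizes are described there. A fit with the summed thalamus and habenula markers as a covariate was also made, and only its result for the glucocorticoid response list is given. The offsets came from a natural spline in each property with 5 degrees of freedom, fitted per library. All 9 value columns of the table were used.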

Results

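Hippocampal messenger RNA was profiled in sham-operated mice, in mice with spinal nerve ligation given solvent (SNL), and in ligated mice given cannabidiol (CBD), with 3 libraries in each group. The expected counts of a library summed to between 16972620 and 20470546. The most abundant gene in every library was mt-Co1, a subunit of mitochondrial cytochrome c oxidase. Mitochondrially encoded genes took 4.03% ± 0.72 (mean ± SD, n = 3) of the counts in sham, 5.52% ± 0.76 in SNL and 5.85% ± 1.16 in CBD. No pair of libraries agreed within sampling noise, and the closest pair, CBD 2 and CBD 3, had a chi-square per gene of 6.59. Libraries also differed in transcripts of regions outside the hippocampus. Pmch, the precursor of melanin-concentrating hormone made in the hypothalamus, stood at 200.4 CPM in SNL 1, 43.9 in SNL 2 and 145.7 in CBD 1, and at 0.797 CPM or less in the other 6 libraries.

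The first comparison, SNL against sham, asks what ligation of a spinal nerve changed in the hippocampus. Genes that glucocorticoid hormones induce were lower in ligated mice. Of 21 genes on the glucocorticoid response list, 19 were lower in SNL, with a median log2 fold change of -0.53. Sgk1, the serum- and glucocorticoid-regulated kinase (ENSMUSG00000019970), stood at 159.6 CPM ± 25.0 in sham and 42.4 CPM ± 9.46 in SNL (n = 3 each). Fkbp5, a co-chaperone of the glucocorticoid receptor (ENSMUSG00000024222), stood at 72.6 CPM ± 16.3 in sham and 35.5 CPM ± 4.72 in SNL. Markers of endothelium and pericytes, markers of thalamus and habenula and genes of the endoplasmic reticulum stress response were higher in SNL. Genes of the postsynaptic scaffold, markers of dentate granule cells and interferon-induced genes were lower. These are calls by camera with a preset correlation. With an estimated correlation these lists and the glucocorticoid response list had an adjusted p from 0.188 to 0.602.

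For single genes, the edgeR test called 0 of 17967 genes in SNL against sham at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 2478, 1048 higher and 1430 lower, where 898 are expected by chance. The DESeq2 Wald test called 363, of which 108 were higher and 255 lower. Those higher included Pmch and the thalamus and habenula markers Tcf7l2, Lef1 and Ntng1. Those lower included the dentate marker C1ql2 and the CA1 marker Nptx1. How far the DESeq2 calls follow the tissue held in each library was not tested. The smallest adjusted p by edgeR was 0.0755, shared by Sgk1 (log2 fold change -1.91, SE 0.23) and Arl4d, a small GTPase (-1.34, SE 0.16). The other genes with the smallest p among those lower in SNL also missed the threshold. They were the potassium channel gene Kcnh1 (-0.81, SE 0.13), the cyclin-like gene Ccnjl (-1.52, SE 0.24) and Fkbp5 (-1.03, SE 0.16), each with an adjusted p of 0.160. Among those higher in SNL, the smallest p-values belonged to Ddit3, a stress-induced transcription factor (0.59, SE 0.10), Klf6 (0.53, SE 0.10), Sh2d1a (0.89, SE 0.18), the caveolin gene Cav1 (0.60, SE 0.12) and Ier3 (1.22, SE 0.26), with adjusted p from 0.193 to 0.210. Every library of one group lay above every library of the other for 17.7% of all genes, where chance gives 10%.

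The glucocorticoid response list fell in SNL by camera (adjusted p 1.54e-08), and fry also passed (adjusted p 0.0214). With an estimated correlation the camera adjusted p was 0.188. Adjusted over the list alone, 12 of the 21 members were lower at an adjusted p under 0.05 and 1, Lcn2, was higher, against 0 when adjusted over all genes. After Sgk1 and Fkbp5, the smallest p-values were those of Hif3a, a hypoxia-inducible factor subunit (log2 fold change -1.85, SE 0.30), and Plin4, a lipid droplet protein (-1.70, SE 0.29). Hif3a stood at 10.9 CPM ± 1.81 in sham and 3.01 CPM ± 0.14 in SNL. Plin4 stood at 11.5 CPM ± 2.70 in sham and 3.54 CPM ± 0.92 in SNL. The list kept its direction and passed camera without any 1 of the 9 libraries, with medians from -0.64 to -0.46.

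**Figure D1:**
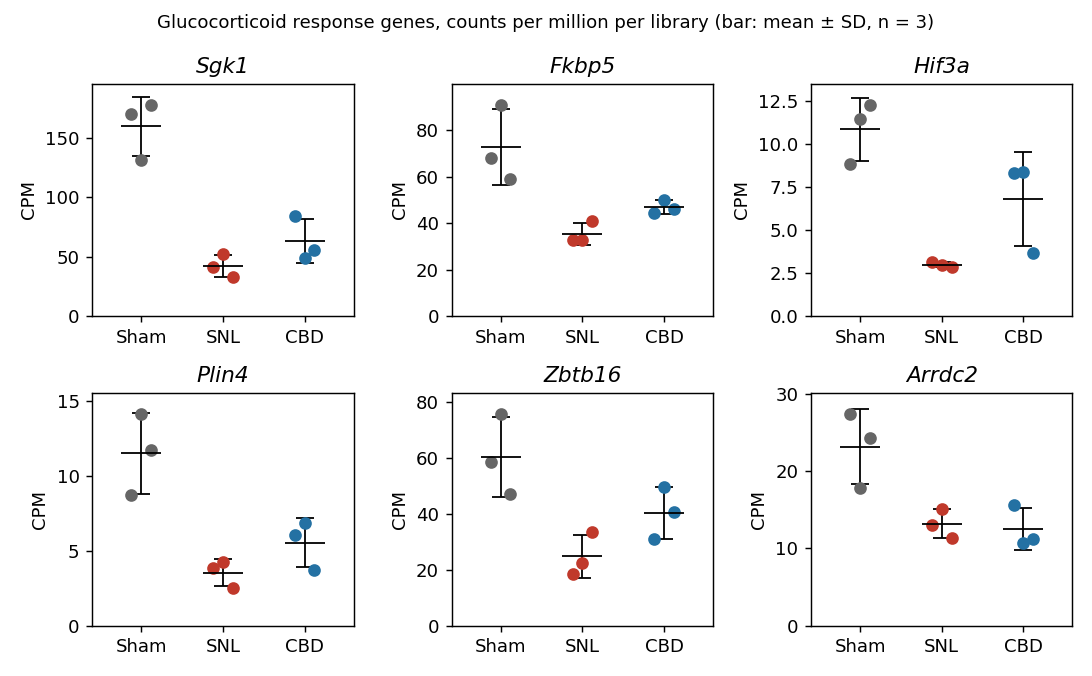
CPM (vertical axis) of 6 glucocorticoid response genes in each library of the sham, SNL and CBD groups (horizontal axis), with dots for libraries and bars for the mean ± SD (n = 3). For Sgk1 the SNL libraries lie between 33.4 and 52.3 CPM and the CBD libraries between 49.1 and 84.2 CPM, below the sham libraries at 131 to 178 CPM.

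Genes of the endoplasmic reticulum stress response rose in SNL, 16 of 18 being higher (median log2 fold change 0.28, camera adjusted p 4.24e-06). The adjusted p was 0.352 with an estimated correlation and 0.0383 by fry. Adjusted over the list alone, 8 members were higher. Ddit3 was 15.3 CPM ± 0.776 in sham and 23.1 CPM ± 0.779 in SNL, and the chaperone gene Hspa5 was 211 CPM ± 22.7 and 299.9 CPM ± 37.5. The log2 fold change was 0.38 (SE 0.10) for Pdia6, a disulfide isomerase, and 0.58 (SE 0.15) for Manf, a secreted neurotrophic factor. Heat shock and protein folding genes also rose by camera (12 of 15 higher, median 0.18, adjusted p 0.0256, and 0.598 with an estimated correlation), a call that was lost without Sham 1 (median 0.09) or without SNL 2 (median 0.185). All 16 endothelial and pericyte markers were higher in SNL (median 0.47, camera adjusted p 5.12e-09, 0.352 with an estimated correlation, and 0.0392 by fry), and 9 passed when adjusted over the list alone. Cldn5, the tight junction protein of brain endothelium, stood at 28.7 CPM ± 5.44 in sham and 46.7 CPM ± 6.86 in SNL, and the log2 fold change was 0.58 (SE 0.13) for the transporter Slco1a4 and 0.56 (SE 0.12) for the pericyte gene Rgs5.

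Lists of postsynaptic genes and of dentate granule and CA1 neurons fell in SNL by camera, while those of CA3 and mossy cells, interneurons, presynaptic release and glutamate receptors did not pass. Of 21 postsynaptic scaffold genes 20 were lower (median -0.46, adjusted p 3.76e-07, and 0.598 with an estimated correlation), and 7 passed when adjusted over the list alone. Cacng8, an auxiliary subunit of AMPA receptors, stood at 99.7 CPM ± 25.9 in sham and 46.3 CPM ± 7.81 in SNL, and the scaffold gene Homer3 had a log2 fold change of -1.13 (SE 0.26). All 14 dentate granule cell markers were lower (median -0.77, adjusted p 7.50e-06, and 0.602 with an estimated correlation), among them C1ql2 at 83.5 CPM ± 25.3 in sham and 41.3 CPM ± 10.7 in SNL, and the median was -0.50 without Sham 2. All 9 CA1 pyramidal markers were lower (median -0.47, adjusted p 0.0011, and 0.598 with an estimated correlation), with Nptx1 at -1.04 (SE 0.31), and the median was -0.75 without SNL 3. With the hypothalamic marker covariate, chosen after seeing the data, the CA1 call was lost at a median of -0.21. Voltage-gated ion channel genes fell (21 of 30 lower, median -0.23, adjusted p 0.00271, and 0.433 with an estimated correlation), with the calcium channel gene Cacna1h at 164.1 CPM ± 43.2 in sham and 82.1 CPM ± 10.2 in SNL. Immediate early genes fell (17 of 21 lower, median -0.28, adjusted p 0.00513, and 0.602 with an estimated correlation), with Egr4 at -1.15 (SE 0.28), a call lost without Sham 1 (median -0.14) or without SNL 3 (median -0.24). The neurotrophin and CREB signalling list fell (11 of 16 lower, median -0.16, adjusted p 0.0116, and 0.433 with an estimated correlation), with a median of -0.33 without SNL 2. The calls for ion channels and neurotrophins were lost with offsets for GC content and length, at medians of -0.10 and -0.15. Over the same libraries all 15 markers of thalamus and habenula were higher (median 1.14, adjusted p 6.45e-08, and 0.433 with an estimated correlation), and 13 passed when adjusted over the list alone. Tcf7l2 stood at 50.2 CPM ± 18.3 in sham and 115.9 CPM ± 40.1 in SNL. Without SNL 2 the median of this list was 0.55. The summed CPM of these markers was at least 819 in each SNL library and at most 704.9 in each sham library. Whether the share of such tissue bears on the falls of the neuronal lists was not examined. A covariate from sums that separate SNL from sham could not settle it.

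The interferon response list fell in SNL, with 19 of 21 genes lower (median -1.25, adjusted p 8.43e-07, and 0.602 with an estimated correlation), and 2 passed when adjusted over the list alone. Irf7, the transcription factor of the type I interferon response, stood at 16.8 CPM ± 3.30 in sham and 3.44 CPM ± 1.12 in SNL (log2 fold change -2.28, SE 0.79). Ifi27 had a log2 fold change of -1.02 (SE 0.20) and Lgals3bp of -1.67 (SE 0.44). Genes of energy metabolism and translation moved by less. All 40 nuclear-encoded oxidative phosphorylation genes were higher (median 0.26, adjusted p 2.84e-07, and 0.602 with an estimated correlation), as were all 13 mitochondrially encoded genes (median 0.42, adjusted p 0.000556, and 0.602 with an estimated correlation). Of 42 cytosolic ribosomal protein genes 40 were higher (median 0.20, adjusted p 0.000165, and 0.841 with an estimated correlation). All 16 myelin genes were higher (median 0.32, adjusted p 0.000267, and 0.664 with an estimated correlation), with Mbp, myelin basic protein, at 4575 CPM ± 644 in sham and 6080 CPM ± 883 in SNL. The ribosomal median was 0.37 without Sham 2, 0.30 without SNL 2 and 0.08 without Sham 1, where the call was lost. The myelin call was lost without SNL 2 at a median of 0.21. The myelin median was -0.01 without the 3 libraries with hypothalamic transcripts, a fit with SNL 3 as the only SNL library. The call for mitochondrially encoded genes was lost with the offsets for GC content and length, at a median of 0.135. Without Sham 1 the oxidative phosphorylation median was 0.13, and without SNL 3 it was 0.17.

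**Figure D2:**
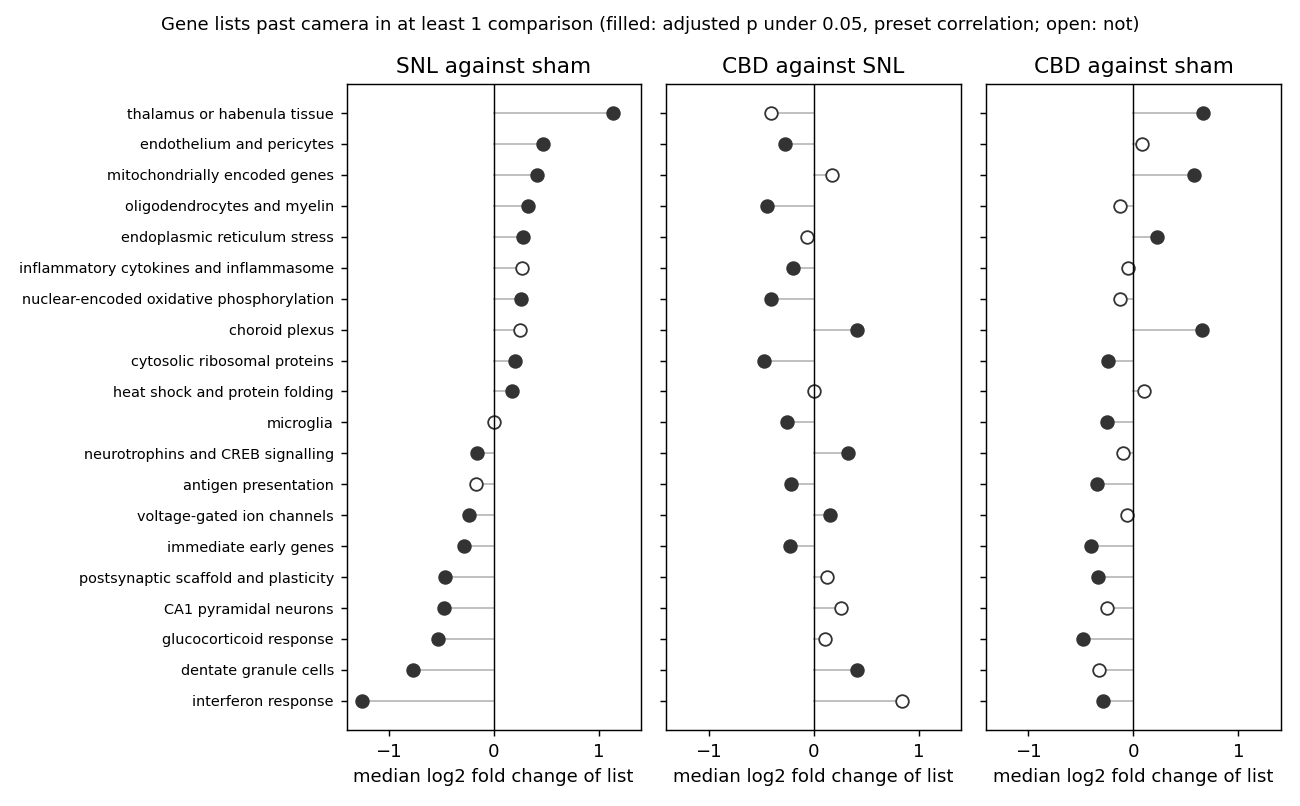
Median log2 fold change (horizontal axis) of the 20 gene lists (vertical axis) that passed camera in at least 1 comparison, filled where the adjusted p was under 0.05 with the preset correlation and open where it was not. The glucocorticoid response list lies at -0.53 in SNL against sham, 0.11 in CBD against SNL and -0.48 in CBD against sham.

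The second comparison, CBD against SNL, asks what cannabidiol changed in ligated mice. Genes for cytosolic ribosomal proteins and for oxidative phosphorylation were lower in CBD, as were markers of endothelium, myelin and microglia, and genes of voltage-gated ion channels were higher. With an estimated correlation the adjusted p was 0.787 for each of these lists, and the ion channel call was lost without SNL 1 or with offsets for GC content and length. Of 42 ribosomal protein genes 40 were lower, with a median log2 fold change of -0.47. Rpl38 stood at 91.9 CPM ± 14.1 in SNL and 56.0 CPM ± 16.9 in CBD (n = 3 each), and Rplp0 at 231.7 CPM ± 5.60 and 176 CPM ± 28.5.

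The edgeR test called 0 of 17967 genes in CBD against SNL, with a smallest adjusted p of 0.306. At an unadjusted p under 0.05 there were 2462, 1168 higher and 1294 lower, against 898 expected, and DESeq2 called 150, 86 higher and 64 lower. The genes with the smallest p, all at an adjusted p of 0.306, were Nr2c2, a nuclear receptor (log2 fold change 0.67, SE 0.10), Xkr4 (0.77, SE 0.13), the neural adhesion gene Ncam2 (0.77, SE 0.14), the DNA polymerase gene Rev3l (0.54, SE 0.10) and the sodium channel gene Scn3a (0.58, SE 0.11) among those higher in CBD. Among those lower they were the microsomal glutathione transferase Mgst3 (-0.78, SE 0.14), Slc35b2 (-0.57, SE 0.11), Josd2 (-0.45, SE 0.09), Ubxn1 (-0.47, SE 0.10) and Bckdha, of branched-chain amino acid breakdown (-0.50, SE 0.11). Nr2c2 stood at 60.1 CPM ± 6.11 in SNL and 95.4 CPM ± 5.98 in CBD, with 87.3 CPM ± 2.67 in sham.

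The ribosomal protein list fell by camera (adjusted p 9.38e-13, and 0.787 with an estimated correlation), and 0 of its members passed when adjusted over the list alone. Of 40 nuclear-encoded oxidative phosphorylation genes 37 were lower (median -0.40, adjusted p 1.03e-11, and 0.787 with an estimated correlation), and 26 passed when adjusted over the list alone. Ndufa2, a subunit of respiratory complex I, stood at 47.4 CPM ± 7.77 in SNL and 27.8 CPM ± 6.72 in CBD, and Ndufs7 had a log2 fold change of -0.57 (SE 0.15). Both lists hold genes with short transcripts, and fold changes in this comparison followed transcript GC content (Spearman rho -0.44 across genes) and length (0.36). Genes are not independent replicates. With offsets that removed both trends, an alternative chosen after seeing the data, the medians were -0.22 for the ribosomal list and -0.21 for the oxidative phosphorylation list, and both still passed camera.

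**Figure D3:**
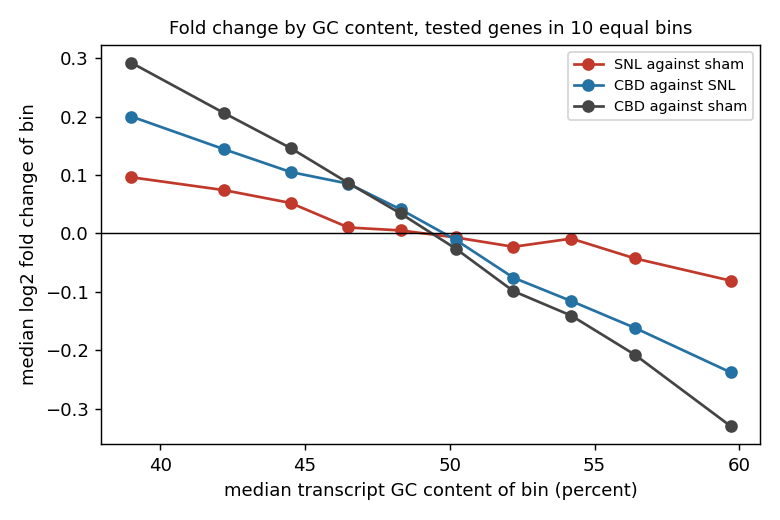
Median log2 fold change (vertical axis) in 10 groups of genes ordered by transcript GC content (horizontal axis), for the 3 comparisons. In CBD against SNL the median runs from 0.20 in the group with the lowest GC content to -0.24 in the group with the highest, and in CBD against sham from 0.29 to -0.33.

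All 16 endothelial and pericyte markers were lower in CBD than in SNL (median -0.27, adjusted p 2.15e-05, and 0.787 with an estimated correlation), with Cldn5 at 28.7 CPM ± 3.02 in CBD, and 5 passed when adjusted over the list alone. All 16 myelin genes were lower (median -0.45, adjusted p 5.12e-05, and 0.787 with an estimated correlation), with Mbp at 4046 CPM ± 235 in CBD. Both medians were smaller without SNL 2, at -0.17 and -0.26. They were -0.21 and -0.19 without the 3 libraries with hypothalamic transcripts, a fit with SNL 3 as the only SNL library. Of 16 microglial markers 15 were lower (median -0.25, adjusted p 0.00242, and 0.787 with an estimated correlation), with log2 fold changes of -0.66 (SE 0.21) for C1qb and -0.41 (SE 0.17) for Trem2, a microglial receptor. Voltage-gated ion channel genes rose (21 of 30 higher, median 0.16, adjusted p 0.0175, and 0.787 with an estimated correlation). The sodium channel gene Scn2a stood at 162 CPM ± 21.1 in SNL and 240.8 CPM ± 14 in CBD. The median of the ion channel list was 0.14 without SNL 1 and 0.07 with the offsets for GC content and length.

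A further 6 lists passed camera in CBD against SNL, each lost without at least 1 of the libraries. Choroid plexus markers were higher (16 of 17, median 0.42, adjusted p 0.0128, and 0.865 with an estimated correlation), and their median was 1.81 without SNL 2, 0.11 without SNL 1 and 0.09 without SNL 3. Dentate granule cell markers were higher (13 of 14, median 0.41, adjusted p 0.0372, and 0.865 with an estimated correlation), with medians of 0.18 without CBD 3, 0.25 without SNL 1 and 0.62 without CBD 1. The neurotrophin and CREB signalling list was also higher (13 of 16, median 0.33, adjusted p 0.0449, and 0.787 with an estimated correlation), with a median of 0.16 without CBD 3. Immediate early genes were lower (18 of 21, median -0.23, adjusted p 0.0175, and 0.787 with an estimated correlation). Their median was -0.15 without SNL 2 and -0.09 with the offsets for GC content and length. Antigen presentation genes were also lower (14 of 16, median -0.22, adjusted p 0.0175, and 0.865 with an estimated correlation). That median was -0.62 without CBD 1, -0.05 without CBD 3 and -0.055 without SNL 2. The offsets ended the calls for immediate early genes, dentate granule cells, neurotrophins and antigen presentation. Inflammatory cytokine and inflammasome genes were lower (16 of 20, median -0.20, adjusted p 0.0343, and 0.787 with an estimated correlation), with Tgfb1, transforming growth factor beta, at 6.01 CPM ± 0.698 in SNL and 3.21 CPM ± 0.623 in CBD.

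The third comparison, CBD against sham, sets ligated mice given cannabidiol beside mice that were never ligated. Glucocorticoid response genes and immediate early genes were lower in CBD, and endoplasmic reticulum stress genes were higher. With an estimated correlation the adjusted p was 0.533 for the first of these lists and 0.670 for the others. All 21 immediate early genes were lower (median log2 fold change -0.40), with Junb at 30.1 CPM ± 6.71 in sham and 16.4 CPM ± 1.88 in CBD (n = 3 each) and Egr4 at 13.5 CPM ± 4.95 and 5.26 CPM ± 1.19. The median GC content of this list was 55.5%. In this comparison the groups of genes with a median GC content of 54.2% and 56.4% had median log2 fold changes of -0.14 and -0.21. Part of the shift of the list may therefore follow GC content. The same holds for the postsynaptic scaffold and antigen presentation lists described below, with a median GC content of 54.7% and 54.4%. Of the 21 glucocorticoid response genes 18 were lower (median -0.48), with Sgk1 at 63.1 CPM ± 18.6 and Fkbp5 at 46.8 CPM ± 2.99 in CBD. Hspa5 stood at 333 CPM ± 7.19 in CBD against 211 CPM ± 22.7 in sham.

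The edgeR test called 0 of 17967 genes in CBD against sham, with a smallest adjusted p of 0.139. At an unadjusted p under 0.05 there were 2925, 1331 higher and 1594 lower, against 898 expected, and DESeq2 called 369, 109 higher and 260 lower. Without CBD 1 the edgeR count was 17. The smallest p belonged to Arl4d (log2 fold change -1.35, SE 0.16, adjusted p 0.139). The others lower in CBD were Sgk1 (-1.34, SE 0.22), the actin-binding gene Twf2 (-0.57, SE 0.10), Bckdha (-0.62, SE 0.11) and the transcriptional corepressor Cbfa2t3 (-0.84, SE 0.14), and those higher were Kantr (0.76, SE 0.13), the calcium-binding protein gene Necab1 (0.83, SE 0.14), Usp53 (0.59, SE 0.11), Hspa5 (0.66, SE 0.12) and Osbpl8 (0.46, SE 0.09). All of these had an adjusted p of 0.213.

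By camera the immediate early genes fell (adjusted p 1.43e-06, and 0.670 with an estimated correlation), and 6 passed when adjusted over the list alone. The glucocorticoid response list fell (adjusted p 2.10e-05, and 0.533 with an estimated correlation), 10 members were lower and 1 higher when adjusted over the list alone, and fry passed with an adjusted p of 0.0367. The member that was higher was Nr3c1, the glucocorticoid receptor itself (log2 fold change 0.54, SE 0.13), while Ddit4 (-1.05, SE 0.21) and Arrdc2 (-0.89, SE 0.20) were among those lower. Endoplasmic reticulum stress genes rose (14 of 18 higher, median 0.22, adjusted p 0.000546, and 0.670 with an estimated correlation), with the chaperone gene Hsp90b1 at 0.53 (SE 0.11). These 3 lists passed camera without any 1 of the 9 libraries. The median of the immediate early genes was -0.63 without Sham 3. Autophagy genes, which camera did not call (adjusted p 0.253), also passed fry (14 of 18 lower, median -0.09, adjusted p 0.0367).

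All 13 mitochondrially encoded genes were higher (median 0.57, adjusted p 3.88e-05, and 0.923 with an estimated correlation), and 7 passed when adjusted over the list alone. The gene mt-Atp6 stood at 325 CPM ± 59.0 in sham and 725.7 CPM ± 372 in CBD. Fold changes in this comparison followed GC content across genes (Spearman rho -0.56), and with the offsets for GC content and length the median of this list was 0.26. The thalamus and habenula markers rose (15 of 15 higher, median 0.66, adjusted p 0.000546, and 0.923 with an estimated correlation), as did the choroid plexus markers (17 of 17 higher, median 0.66, adjusted p 0.00352, and 0.923 with an estimated correlation). Without Sham 2 the first of these medians was 0.40, and the choroid plexus call was lost at a median of 0.315. Without Sham 1 the choroid plexus median was 1.09. Postsynaptic scaffold genes fell (18 of 21 lower, median -0.34, adjusted p 0.00145, and 0.923 with an estimated correlation), with Cacng8 at 47.9 CPM ± 6.57 in CBD, a call lost without CBD 1 at a median of -0.255. Microglial markers fell (14 of 16 lower, median -0.25, adjusted p 0.00352, and 0.923 with an estimated correlation), with Tmem119 at 26.7 CPM ± 2.88 in sham and 18.1 CPM ± 4.22 in CBD, a call lost without Sham 2 at a median of -0.14. Antigen presentation genes fell (median -0.35, adjusted p 0.00352, and 0.923 with an estimated correlation), with the histocompatibility gene H2-D1 at 86.5 CPM ± 12.8 in sham and 56.8 CPM ± 10.6 in CBD. Single libraries set the size of this shift, with medians of -0.74 without CBD 1, -0.22 without CBD 2 and -0.06 without CBD 3, where the call was lost. Ribosomal protein genes fell (38 of 42 lower, median -0.25, adjusted p 0.00145, and 0.923 with an estimated correlation), with medians of -0.41 without CBD 1, -0.08 without Sham 2 and -0.15 without CBD 3, the last 2 ending the call.

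The interferon response list was lower in CBD than in sham (17 of 21, median -0.29, adjusted p 0.00352, and 0.923 with an estimated correlation), and single libraries set its size. The summed CPM of the list was 446, 412 and 547 in the sham libraries, 198, 283 and 205 in the SNL libraries, and 673, 189 and 200.2 in the CBD libraries. Without CBD 1 the median was -1.51. Without Sham 3 it was -0.08, without CBD 2 0.07 and without CBD 3 0.03, and each of these ended the call. In CBD against SNL the list had a median of 0.84 and a camera adjusted p of 0.0809, and without CBD 1 the median was -0.23.

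**Figure D4:**
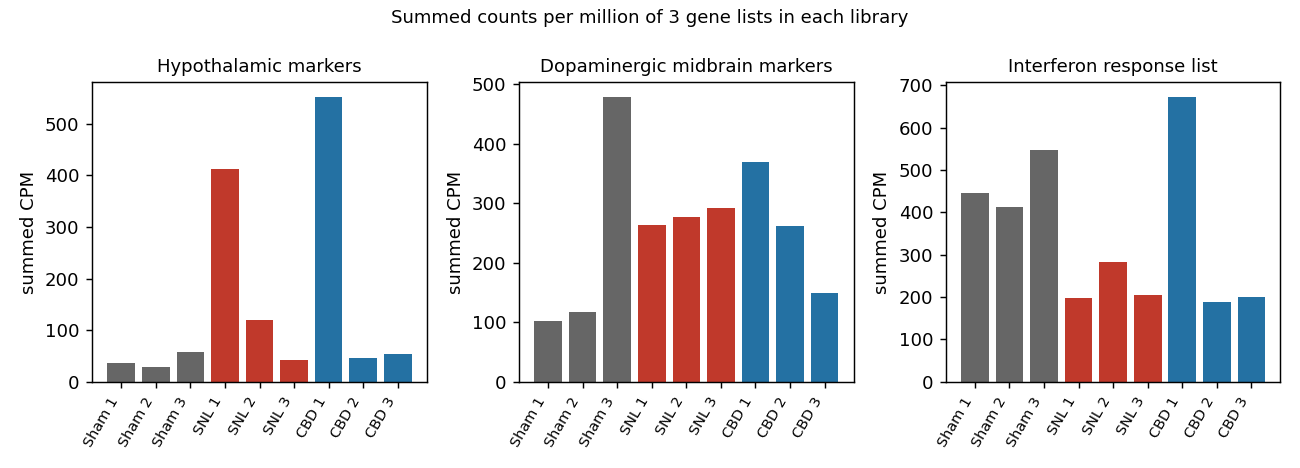
Summed CPM (vertical axis) in each library (horizontal axis) of the hypothalamic markers, the dopaminergic midbrain markers and the interferon response list, with bars coloured by group. The hypothalamic sum is 413 CPM in SNL 1 and 553 CPM in CBD 1 and at most 119 CPM in the other libraries, and the interferon sum is highest in CBD 1 and the sham libraries.

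The comparisons together ask whether genes that differed after ligation moved back under cannabidiol. Of the 12 glucocorticoid response genes lower in SNL than in sham at an unadjusted p under 0.05, 10 were higher in CBD than in SNL, 6 of them at an unadjusted p under 0.05, and all 12 were lower in CBD than in sham, 10 of them at an unadjusted p under 0.05. Genes picked for low SNL values tend to stand higher in any group set against SNL. In 200 simulations in which CBD and SNL had the same mean, chosen after the result was seen, between 8 and 17 genes were picked. A mean of 54.7% of them were higher in CBD, against 83.3% observed, a share reached in 1 simulation, and 10 or more were higher in 19 simulations. A mean of 0.64 were higher at an unadjusted p under 0.05, with at most 4 in a simulation. A mean of 12.4 of 12.4 picked genes were lower in CBD than in sham, so all 12 being lower is what no change between SNL and CBD gives. The simulations drew each gene on its own, so they leave out the correlation between genes of the list. Hif3a stood at 6.80 CPM ± 2.73 in CBD (log2 fold change against SNL 1.18, SE 0.30, adjusted p 0.306) and Zbtb16, a zinc finger transcription factor, at 24.9 CPM ± 7.75 in SNL and 40.4 CPM ± 9.29 in CBD (0.70, SE 0.25, adjusted p 0.313). The list as a whole had a median of 0.11 in CBD against SNL and did not pass camera (adjusted p 0.134).

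No gene passed the edgeR threshold in either SNL against sham or CBD against SNL, so the number changed in opposite directions was 0 by construction. DESeq2 called 16 genes in both, all in opposite directions, 12 lower in SNL and higher in CBD against 1.70 expected of independent lists, and 4 the other way against 0.47. They include Hif3a, Nr2c2 and Cldn5. The SNL libraries stand in both comparisons, and 3 libraries cannot be split into parts of 2 or more, so part or all of this excess may come from sharing them. The overlap of DESeq2 calls was not simulated with shared libraries. Across the 17967 genes the log2 fold changes of both comparisons had a Pearson r of -0.44, and genes are not independent replicates. In 50 simulations, unchanged groups that shared the SNL libraries gave r between -0.53 and -0.47, with a mean of -0.50. The covariance was -0.0708 against a simulated mean of -0.0587, with a simulated range of -0.0666 to -0.0544. The difference was -0.0121. Opposite signs in both comparisons were found for 64.4% of genes, below the 65.8% to 67.5% of the simulations. The r and the share of opposite signs were thus weaker than simulated, while the covariance was larger in size. These simulations also drew each gene on its own, so their ranges leave out the correlation between genes. The covariance therefore cannot show that genes moved back under cannabidiol.

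The anchor genes showed no call in any comparison by edgeR. Bdnf, brain-derived neurotrophic factor, stood at 33.2 CPM ± 8.70 in sham, 22.3 CPM ± 4.01 in SNL and 27.7 CPM ± 8.34 in CBD. The cannabinoid receptor gene Cnr1 stood at 117.6 CPM ± 19.8, 92.9 CPM ± 34.1 and 130.3 CPM ± 10.3 in these groups, and Faah, whose product breaks down anandamide, at 153.9 CPM ± 37.9, 102 CPM ± 22.7 and 109.9 CPM ± 32.1. The serotonin receptor gene Htr1a stood at 29.1 CPM ± 3.27, 20.01 CPM ± 5.96 and 26.1 CPM ± 3.07. The astrocyte gene Gfap and the microglial gene Aif1 had log2 fold changes in SNL against sham of -0.18 (SE 0.15) and 0.25 (SE 0.28). Fos and Arc had 0.79 (SE 0.41) and -0.15 (SE 0.20), and Ttr and Drd2 had 0.27 (SE 0.86) and 0.36 (SE 0.62). The cannabidiol-sensitive channel gene Trpv1 and the cytokine genes Il1b and Tnf were too low to be tested, with group means of at most 0.162 CPM for Trpv1, 0.237 CPM for Il1b and 0.106 CPM for Tnf. The list of endocannabinoid genes and cannabidiol targets did not pass camera in any comparison, with 16 of 26 lower in SNL against sham (median -0.12, adjusted p 0.665), 17 of 26 higher in CBD against SNL (median 0.08, adjusted p 0.838) and 17 of 26 lower in CBD against sham (median -0.14, adjusted p 0.426).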

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

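Every group held 3 libraries. The cause of the shifts below was not tested. Offsets for GC content and length, the hypothalamic marker covariate and the fit without the 3 libraries with hypothalamic transcripts were chosen after seeing the data. That fit leaves SNL 3 as the only SNL library, so its values for comparisons with SNL rest on that library.

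Genes changed numbered 0 by edgeR in SNL against sham, CBD against SNL and CBD against sham, in that order. With no filter on low counts they numbered 253, 1 and 56, by the DESeq2 Wald test 363, 150 and 369, and by limma voom with sample weights 1, 1132 and 1051. The voom weight was 4.27 for CBD 2, 0.45 for CBD 1 and at most 1.36 for the other libraries. DESeq2 gave 16 genes changed in opposite directions in the first 2 comparisons. With only the 6 libraries compared CBD against sham had 1, and SNL against sham had 1 with a surrogate variable and 2 at an adjusted p under 0.1. Without CBD 1 the counts were 8, 2 and 17. SNL against sham had 7 without Sham 3 and 1 without CBD 3, and CBD against sham had 1 without SNL 2. With the hypothalamic marker covariate SNL against sham had 1. Without the 3 libraries CBD against sham had 20, and no counts are given for the comparisons with SNL 3 alone. The correlation of fold changes, -0.44, ran from -0.60 to -0.36 with 1 library left out, and was -0.56 without SNL 2, -0.60 without SNL 3 and -0.63 without the 3 libraries.

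The replicate block, which pairs libraries by the number in their titles, gave 0 genes in each comparison and 16, 11 and 13 lists. Lists past camera numbered 16, 12 and 11 with the preset correlation, 0, 0 and 0 with an estimated correlation, and 3, 0 and 2 by fry. With each library left out in turn they numbered 13 to 21, 9 to 15 and 9 to 14, and 12 of the 16, 5 of the 12 and 5 of the 11 lists passed every time. Under every setting but the estimated correlation and fry, 8, 3 and 5 lists passed, with the fit on SNL 3 alone among these settings. Calls in SNL against sham ended for myelin without SNL 2, immediate early genes without Sham 1 or SNL 3, heat shock without Sham 1 or SNL 2, and ribosomal proteins without Sham 1. In CBD against SNL they ended for choroid plexus without SNL 1, SNL 3 or CBD 2, dentate granule cells without Sham 1, SNL 1, CBD 2 or CBD 3, immediate early genes without SNL 2 or CBD 1, neurotrophins without Sham 1, SNL 1, SNL 2, CBD 1 or CBD 3, ion channels without SNL 1, cytokines without SNL 2, SNL 3 or CBD 2, and antigen presentation without SNL 2, CBD 2 or CBD 3. In CBD against sham they ended for microglia and choroid plexus without Sham 2, the postsynaptic scaffold without CBD 1, interferon without Sham 3, CBD 2 or CBD 3, antigen presentation without CBD 3, and ribosomal proteins without Sham 2 or CBD 3. Other medians moved by over 1.5 times. In SNL against sham these were myelin (0.211 without Sham 1, 0.534 without Sham 3), immediate early genes (-0.142 without Sham 1) and heat shock (0.094 without Sham 1, 0.275 without Sham 3). In CBD against SNL they were immediate early genes (-0.146 without SNL 2, -0.34 without CBD 3), ion channels (0.266 without CBD 1), cytokines (-0.099 without SNL 2, -0.128 without CBD 2) and antigen presentation (-0.426 without SNL 1, -0.139 without CBD 2). In CBD against sham they were microglia (-0.139 without Sham 2, -0.16 without CBD 3) and the postsynaptic scaffold (-0.224 without Sham 1, -0.509 without Sham 3). The GC and length offsets ended the calls for neurotrophins, ion channels and mitochondrially encoded genes in SNL against sham and for dentate granule cells, immediate early genes, neurotrophins, ion channels and antigen presentation in CBD against SNL. A surrogate variable ended those for myelin, immediate early genes and heat shock in SNL against sham and for dentate granule cells, cytokines and antigen presentation in CBD against SNL. The hypothalamic marker covariate ended those for myelin, CA1 neurons and heat shock in SNL against sham, cytokines in CBD against SNL and the postsynaptic scaffold in CBD against sham. Without the 3 libraries those for myelin and heat shock ended in SNL against sham, those for myelin, endothelium, immediate early genes and neurotrophins in CBD against SNL, and that for the postsynaptic scaffold in CBD against sham. The replicate block ended the call for neurotrophins in CBD against SNL (0.29).

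Signs turned for some genes and lists, none of them past the threshold with all libraries except the myelin list in SNL against sham and the interferon list in CBD against sham. By voom, Gfap (-0.10) and Drd2 (0.18) in CBD against SNL had 0.011 and -0.175, and Ifit2 (0.44) in CBD against sham had -0.006. With the replicate block Ttr (0.27) in SNL against sham had -0.29. With a surrogate variable Arc (-0.15) and Drd2 (0.36) in SNL against sham had 0.12 and -0.29, Faah (0.11) in CBD against SNL had -0.07, and Ifit2 and Drd2 (0.54) in CBD against sham had -0.037 and -0.014. With the GC and length offsets Gfap in CBD against SNL had 0.052, and Cnr1 (0.15) and Aif1 (-0.09) in CBD against sham had -0.011 and 0.009. With the hypothalamic marker covariate Arc and Drd2 in SNL against sham had 0.081 and -0.154, and Ifit2 and Drd2 in CBD against sham had -0.184 and -0.073. Without the 3 libraries SNL held SNL 3 alone. In that fit Cnr1 (-0.34), Fos (0.79) and Ttr in SNL against sham had 0.11, -0.40 and -1.62, and the myelin list (0.32) had -0.012. Drd2 and the interferon list (0.84) in CBD against SNL had -0.42 and -0.042, and Ifit2 and Drd2 in CBD against sham had -0.19 and -0.12. With 1 library left out, Ttr and Drd2 in SNL against sham ran from -1.30 to 0.83 and from -0.007 to 1.33. Faah, Drd2 and the interferon list in CBD against SNL ran from -0.079 to 0.31, -0.50 to 0.60 and -0.23 to 1.09. Aif1, Ifit2, Drd2 and the interferon list in CBD against sham ran from -0.35 to 0.17, -0.20 to 0.74, -0.13 to 1.51 and -1.51 to 0.075.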

Other observations

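The tests chosen after the result was seen were the ratio of clock genes, the bound on hypothalamic sums from sham, the offsets as a test of GC content as the whole cause and the divisions counted for edgeR genes at an adjusted p under 0.05, and the offsets and both marker covariates were added after seeing the data.

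Glucocorticoid response genes were lower in SNL than in sham, with a median log2 fold change of -0.53. With the hypothalamic marker score as a covariate the median was -0.51 (camera adjusted p 5.03e-11), with offsets for GC content and length it was -0.44 (2.48e-09), and with the summed thalamus and habenula markers as a covariate it was -0.58 (1e-07). The values with the hypothalamic score and with the offsets argue against hypothalamic tissue or a GC trend as the whole source. These camera p-values rest on the preset correlation. The thalamus and habenula sums were at least 819 CPM in each SNL library and at most 704.9 CPM in each sham library. That covariate therefore cannot separate thalamic tissue from ligation, and thalamic tissue stays open. The log2 ratio of the clock genes Dbp and Arntl differed by 0.12 (SE 0.16) between SNL and sham. It ran from 1.36 to 1.80 in SNL and from 1.41 to 1.67 in sham. Per1, Per2, Per3 and Tef were lower in SNL at an unadjusted p under 0.05. These are 4 of 18 clock genes, against 2478 of all 17967 genes at that p, and Per1 is also on the glucocorticoid response list. A difference in time of day between SNL and sham stays open. The ratio was 1.59 in CBD 1, 0.67 in CBD 2 and 0.54 in CBD 3. Time of day may thus also differ in the comparisons with CBD, which was not tested. A lower glucocorticoid level, a difference in handling or killing and a change in the cells sampled stay open, as hormone levels are not part of the data.

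Hypothalamic neuropeptide transcripts were high in SNL 1, SNL 2 and CBD 1. For 15 hypothalamic genes not looked at before they were listed, log2(CPM + 0.1) in these libraries exceeded the other 6 by a median of 1.83, and 15 of 15 were above 0. By library the median was 2.40 in SNL 1 and 2.91 in CBD 1, as some hypothalamic tissue in these would give, and 0 in SNL 2. Genes above every one of the other 6 libraries numbered 14 of 15 in SNL 1, 13 in CBD 1 and 4 in SNL 2. The source of the transcripts in SNL 2 stays open. Of the 6 ligated libraries 3 had a summed CPM of hypothalamic markers at or below the highest sham library, 57.9, which restates the pattern, so an effect of ligation on these genes in some animals stays open. The midbrain sum was highest in Sham 3 (478.9 CPM) and next in CBD 1 (368.2), and the choroid plexus sum was highest in SNL 2 (3488) and next in CBD 2 (3041) with 830.6 in SNL 1, so neither rose in these 3 libraries alone.

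Cytosolic ribosomal protein genes were lower in CBD than in SNL, with a median of -0.47. With the GC and length offsets the median was -0.22 (camera adjusted p 1.82e-08), less than 50% of its size without them. A trend in library composition may therefore be part of the cause. The list still passed, but this cannot exclude the trend as the whole cause. The offsets are smooth fits on transcripts of an older annotation and may leave part of a trend. The camera p also rests on the preset correlation. The median nearest 0 with 1 SNL or CBD library left out was -0.38, and 6 of 6 such fits kept more than 50% of the shift, which argues against 1 library as the source. An effect of cannabidiol and a difference in RNA or library preparation between the groups stay open.

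The 6 libraries of a comparison can be divided into groups of 3 in 10 ways, too few for a share under 0.05. In SNL against sham the real division gave 0 edgeR genes at an adjusted p under 0.05 (highest other 0, 10 of 10 divisions with as many), 2478 at an unadjusted p under 0.05 (highest other 2875, 2 of 10), 363 DESeq2 genes (598, 2 of 10) and 16 lists (16, 2 of 10). In CBD against SNL it gave 0 (2, 10 of 10), 2462 (2709, 2 of 10), 150 (516, 2 of 10) and 12 lists (13, 5 of 10). In CBD against sham it gave 0 (8, 10 of 10), 2925 (1751, 1 of 10), 369 (67, 1 of 10) and 11 lists (17, 6 of 10). The division that gave 516 set CBD 1, SNL 1 and SNL 2, the libraries with hypothalamic transcripts, against the rest, and the one that gave 598 set SNL 1, SNL 2 and Sham 3 against the rest.

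The lists that passed camera in no comparison had the following median log2 fold changes in SNL against sham. Among cell and tissue lists they were 0.02 for astrocytes, 0.22 for oligodendrocyte precursors, -0.03 for ependyma and cilia, -0.15 for meningeal fibroblasts, 0.02 for blood, -0.41 for CA3 and mossy cells, -0.05 for GABAergic interneurons, 0.12 for striatal tissue and 0.04 for cortical tissue. Among signalling lists they were -0.16 for glutamate receptors, 0.08 for GABA receptors and transport, 0.02 for monoamine receptors and metabolism, 0.29 for neuropeptides and opioids and -0.07 for presynaptic vesicle release. Among the rest they were 0.07 for reactive astrocytes, 0.00 for the circadian clock, 0.12 for oxidative stress and ferroptosis, 0.15 for cholesterol synthesis and uptake, 0.06 for adult neurogenesis, -0.04 for apoptosis and cell death, 0.04 for autophagy, -0.04 for drug metabolism and -0.14 for RNA quality and nuclear RNA. The smallest camera adjusted p among all of these, over the 3 comparisons, was 0.0519, for GABA receptors and transport in CBD against sham.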
